A study of Rattus norvegicus with 24 samples.

How the data were processed

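Gene expression was measured in the cerebellum of Sprague-Dawley rats on 24 Affymetrix arrays, with total RNA made into single-stranded DNA, fragmented and labelled with biotin using the WT Plus kit, per the labels' protocols. The 5 groups were sham surgery (Sham, n = 5), portocaval anastomosis (PCA, n = 5), and PCA with repeated infusions of ammonia (NH3, n = 5), lipopolysaccharide (LPS, n = 5) or both (NH3 + LPS, n = 4). The labels do not say whether numbered samples of a group are separate animals, so each p-value measures the spread between these samples. They give no batch or date, and whether the Sham and PCA groups received vehicle infusions is not given in the sources used here.

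The values deposited by the authors were log2 expression values made with RMA, per the submitters' processing notes. RMA stands for background correction, quantile normalization and a summary per probe set. Its version, the annotation build and any filters are not given in the sources used here. Every value was a multiple of 0.1 between 1.5 and 13.5 (tolerance 1e-06 of a step), which adds a rounding SD of 0.029. The annotated table and the series matrix held the same values, with 0 differences. Arrays give no read depth, and the number of arrays limits the precision: the median standard error (SE) of a log2 difference was 0.099 between 2 groups of 5 arrays and 0.072 for the factor contrasts described next.

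Of the 29016 probe sets, 19338 carried 1 gene symbol, 1521 carried several and 8157 carried none. Among those with 1 symbol, 14126 had a current symbol in the rat RefSeq table, 3362 were updated from an older synonym and 1850 were kept as given. For the 817 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 18161 genes.

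All 24 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with its default empirical Bayes step and no covariates. Sharing the fit gave 19 residual and 4.39 prior degrees of freedom. The contrasts were PCA, NH3, LPS and NH3 + LPS each against Sham, NH3, LPS and NH3 + LPS each against PCA, and the mean of the 4 PCA groups against Sham. The ammonia factor was the mean of the NH3 and NH3 + LPS groups against the mean of the PCA and LPS groups, the LPS factor was the mean of the LPS and NH3 + LPS groups against the mean of the PCA and NH3 groups, and an interaction tested whether the combination differed from the sum of both. A moderated F-test asked whether any of the 5 groups differed. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and intervals are at 95%.

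The 29 gene lists of cell types and pathways were tested with camera of limma at its preset correlation of 0.01, with adjustment over the lists within each contrast. Repeating camera with an estimated correlation, and fry of limma (statmod 1.5.0), gave the alternatives. Counts within a list are also given adjusted over the list alone, with their range over the 24 fits that left out 1 array. A list's mean per array is the mean of its genes after subtracting each gene's mean over all arrays. Fold changes of contrasts that share the PCA arrays were compared by Pearson correlation and covariance across genes. They are set beside 100 draws of unchanged groups that share the same arrays, and beside 20 fits in which separate PCA arrays served each contrast.

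The groups, contrasts, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. That rule took, for PCA, NH3 + LPS and all PCA groups against Sham and for each infusion group against PCA, all genes past the threshold and then those of smallest p up to 10, without symbols that start with LOC, RGD, AABR, Mir, Olr, Vom, Snor or Rn (where 10 or more passed, it would have taken 12 in each direction). It added up to 4 members of smallest p in each list described, and 15 genes of prior interest, of which Glul had no probe set under its own symbol. Some genes that the rule names are not described here. Called genes outside this rule are named and marked as chosen after their values were seen.

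The fit was tested on simulated arrays with the real gene means and spreads and 200 changed genes of 18161, over 10 draws. For the contrast of LPS against PCA, 71.5% of genes changed by 0.5 on the log2 scale were recovered, 96.9% at 1 and 98.8% at 1.5, with 5.2% false calls. For the LPS factor these shares were 88.8%, 98.1% and 99.8%, with 5.1% false calls. For all PCA groups against Sham they were 87.2%, 98.1% and 99.4%, with 5.6% false calls. With 200 genes changed, the adjusted threshold is easier to pass than in the real contrasts, where few genes passed. These shares therefore do not measure the recovery of genes there. In simulated LPS against PCA contrasts over 18161 genes, camera found a list shifted by 0.5 in 20 of 20 draws. The simulated genes varied independently of each other, so these draws do not measure false calls of lists in the real arrays, where other splits of the samples called up to 22 of 29 lists.

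The alternatives were the other table, an intensity trend with robust settings, array weights, filters leaving out 25% or 50% of genes by mean expression, all probe sets, cyclic loess, the sample number as a block, the choroid plexus mean as a covariate, only the groups of a contrast, and leaving out each of the 24 arrays in turn. The other table held the same values, so its results were fixed in advance. Sham arrays do not enter the ammonia or LPS factor. Leaving 1 of them out could thus change only the shared spread there, not the log2 difference. A myelin covariate, leaving out 4 arrays with choroid plexus markers or 3 with brainstem markers, and added rounding noise were chosen after seeing the data. Probe sets with several symbols or none were left out of the gene test because their signal could not be given to 1 gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.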

Results

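Expression of 18161 genes was measured in rat cerebellum on 24 arrays in a model of hepatic encephalopathy, the brain disorder that follows liver failure or shunting. Portocaval anastomosis (PCA) connects the portal vein to the vena cava, so that portal blood bypasses the liver. The tissue was taken 6 months after PCA. The infused groups received 10 infusions at an interval of 2 weeks, of ammonia (NH3) at 20 µl/min for 3 h, of lipopolysaccharide (LPS, a bacterial cell wall component that activates innate immunity) at 5 mg/kg, or of both. There were 5 arrays each for Sham, PCA, NH3 and LPS, and 4 for NH3 + LPS. Values are log2 expression, and group values are means ± SD. The number of arrays limits the precision.

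The mean of the 4 PCA groups against Sham asked what the shunt changed with or without infusions. LOC100362769, whose symbol also stands on probe sets labelled with the metallothionein gene Mt1a, rose by 0.70 (SE 0.11, limma adjusted p = 0.0477), and all 19 arrays with PCA lay above the mean of the 5 Sham arrays. It was chosen after its values were seen, and its level was 7.56 ± 0.15 in Sham (n = 5) and 8.14 ± 0.28 in PCA alone (n = 5). Genes named by the rule that did not pass were Fmo2, a flavin monooxygenase that oxidizes foreign compounds, at 0.95 (SE 0.20), Pla1a, a phosphatidylserine phospholipase, at 0.72 (SE 0.16), and Fxyd1, a regulator of the sodium pump, at 0.34 (SE 0.07). Also not passing were Ttyh1, a glial and neuronal anion channel protein, at -0.32 (SE 0.06), and Edn1, the vasoconstrictor endothelin, at -0.43 (SE 0.10). The other genes of the rule were Adgre1 at 0.58, Cyp2j3 at 0.43, Zscan26 at 0.26, Desi2 at 0.19 and Tg at -0.27, and the smallest limma adjusted p among all 10 was 0.193 for Ttyh1.

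Among the gene lists in that contrast, complement genes were higher by a median of 0.296 (8 of 10 positive, camera adjusted p = 0.000107, adjusted p = 0.693 with an estimated correlation). Adjusted over the list alone 3 of them rose (0 to 5 without 1 array, 0 without Sham array 2 or 4), against 0 over all genes, with C3, the central complement protein, at 0.85 (SE 0.25) and C1qb at 0.34 (SE 0.12). C3 was at 7.56 in Sham and 7.68 in PCA alone, against 9.40 in LPS and 9.18 in NH3 + LPS, so its difference came with LPS. The complement mean per array was -0.24 ± 0.27 in Sham, -0.08 ± 0.19 in PCA, -0.10 ± 0.15 in NH3 and 0.36 ± 0.28 in LPS (n = 5 each), and 0.07 ± 0.17 in NH3 + LPS (n = 4). Microglial genes had a median of 0.176 (16 of 18 positive, camera adjusted p = 0.000107, adjusted p = 0.693 with an estimated correlation), with Ptprc at 0.47 (SE 0.19) but at 0.01 (SE 0.07) by its other, dimmer probe set. Immediate early genes, which respond to neuronal activity, had a median of -0.172 (13 of 15 negative, camera adjusted p = 0.00435, adjusted p = 0.693 with an estimated correlation), with Nr4a3 at -0.89 (SE 0.29) and Egr1 at -0.35 (SE 0.13). Brainstem markers were lower in the same contrast, with a median of -0.165 (camera adjusted p = 0.000402, adjusted p = 0.693 with an estimated correlation), as were myelin genes at -0.15 (camera adjusted p = 0.0444, adjusted p = 0.763 with an estimated correlation). Both rested on Sham array 1, which had the highest mean of either list: without it the brainstem median was -0.021 (camera adjusted p = 0.342), and the myelin median turned to 0.107 (camera adjusted p = 0.0196). The myelin call also ended without any 1 of 12 other arrays (camera adjusted p up to 0.153). The microglial call ended without Sham array 2 (median 0.097, camera adjusted p = 0.0583) and the immediate early call without Sham array 3 (median -0.048, camera adjusted p = 0.372). Meninges and fibroblast genes had a median of 0.173 (11 of 14 positive, camera adjusted p = 0.0373, adjusted p = 0.71 with an estimated correlation), but 0.011 without Sham array 1 (camera adjusted p = 0.342) and -0.036 without Sham array 2 (camera adjusted p = 0.836), and their call held in 13 of 24 fits that left out 1 array. Sham array 2 had the lowest mean of all 24 arrays for this list (-1.22), for complement genes (-0.57) and for microglial genes (-0.43). In all, 11 of 29 lists passed in this contrast, and 0 did with an estimated correlation. The call of LOC100362769 held in 6 of 24 fits that left out 1 array.

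PCA alone against Sham asked what the shunt changed without infusions. No gene passed (0 of 18161 with limma, 651 at an unadjusted p under 0.05, smallest adjusted p 0.986). By chance 908 genes are expected at that unadjusted p in each contrast. Of 100 splits of these arrays, the real one included, 82 gave 651 or more. The genes of smallest p were Ttyh1 at -0.36 (SE 0.08), Edn1 at -0.56 (SE 0.13), Fmo2 at 1.10 (SE 0.25), Sertad4 at -0.48, Best1 at -0.32, Pla1a at 0.80 (SE 0.20), Gzmn at 0.32, Obox5 at 0.40, Desi2 at 0.22 and B3galt2 at 0.34, with n = 5 in each group. Cholesterol synthesis genes had a median of -0.18 with 14 of 15 negative (camera adjusted p = 3.82e-06, adjusted p = 0.462 with an estimated correlation). Of these, 2 fell adjusted over the list alone (0 to 3 without 1 array, 0 without Sham array 1 or PCA array 1, and 1 with cyclic loess) and 0 over all genes: Sc5d at -0.22 (SE 0.06) and Fdft1, which makes squalene, at -0.26 (SE 0.09). Heat shock and unfolded protein genes had a median of 0.10 (14 of 17 positive, camera adjusted p = 0.000132, adjusted p = 0.462 with an estimated correlation). Microglial genes had one of 0.18 (17 of 18 positive, camera adjusted p = 0.000132, adjusted p = 0.823 with an estimated correlation). Immediate early genes had a median of -0.26 (11 of 15 negative, camera adjusted p = 0.0033, adjusted p = 0.823 with an estimated correlation), with Fos at -0.98 (SE 0.38) and Egr1 at -0.46 (SE 0.17). Myelin genes, all 17 negative, had a median of -0.16 (camera adjusted p = 0.00283, adjusted p = 0.846 with an estimated correlation). The Sham array with the highest myelin mean lay at 1.13 against a group mean of 0.12 ± 0.60 (n = 5). Without that array, Sham array 1, the myelin median turned to 0.05 (camera adjusted p = 0.539), and the cholesterol synthesis median was -0.05 (camera adjusted p = 0.0639). The myelin call also ended without PCA array 1 or 5 (camera adjusted p = 0.0672 and 0.06), the microglial call without Sham array 2 or PCA array 3 (0.0558 and 0.075), and the immediate early call without Sham array 3 or PCA array 3 (0.176 and 0.075).

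The ammonia factor asked what repeated ammonia changed across both groups that received it, 9 arrays against 10. Per2, a repressor of the circadian clock, fell by 0.93 on the log2 scale (SE 0.14, 0.523-fold, limma adjusted p = 0.00863), and all 9 ammonia arrays lay below the mean of the 10 others. Its level was 8.08 ± 0.19 in PCA and 8 ± 0.22 in LPS (n = 5 each), against 7.26 ± 0.46 in NH3 (n = 5) and 6.95 ± 0.35 in NH3 + LPS (n = 4). In NH3 + LPS, Per2 was further below PCA than below Sham (both differences are given below). The PCA level itself thus lay above Sham, and the fall with ammonia is not a fall of that size from Sham. Dusp4, a phosphatase that switches off MAP kinases, fell by 0.70 (SE 0.12, limma adjusted p = 0.0287). Lyn, a Src-family kinase of myeloid cells, fell by 0.41 (SE 0.07, limma adjusted p = 0.0434), and both genes were below that mean in 9 of 9 arrays. All 3 were chosen after their values were seen. Without the 4 arrays with choroid plexus markers none of the 3 passed, with Per2 at -0.87 (SE 0.15, limma adjusted p = 0.169), Dusp4 at -0.67 (SE 0.14, limma adjusted p = 0.719) and Lyn at -0.35 (SE 0.09, limma adjusted p = 0.926). Over the alternatives other than single arrays, the adjusted p ranged from 0.00374 to 0.169 for Per2, from 0.0101 to 0.719 for Dusp4 and from 0.0269 to 0.926 for Lyn. In the 24 fits that left out 1 array, Per2 passed in 24, Dusp4 in 15 and Lyn in 7.

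Heat shock and unfolded protein genes fell with ammonia as a group, with a median of -0.16 and 14 of 17 negative (camera adjusted p = 4.44e-12, adjusted p = 0.00895 with an estimated correlation, fry adjusted p = 0.00144). Adjusted over the list alone 10 of them fell (8 to 11 without 1 array), against 0 over all genes. They included Hspb1, a small heat shock protein, at -0.56 (SE 0.14), Hspa5, the main chaperone of the endoplasmic reticulum, at -0.30 (SE 0.08), Dnajb1, a cochaperone, at -0.26 (SE 0.07), and Pdia4, a disulfide isomerase, at -0.24 (SE 0.05). The list's mean per array was -0.05 ± 0.05 in NH3 (n = 5) and -0.13 ± 0.02 in NH3 + LPS (n = 4), against 0.10 ± 0.10 in PCA and 0.07 ± 0.11 in LPS (n = 5 each). Sham lay at -0.02 ± 0.03 (n = 5), near NH3 and below PCA and LPS. The fall is thus one from PCA and LPS, and in NH3 not one of that size from Sham. Cholesterol synthesis genes had a median of 0.188 with 14 of 15 positive (camera adjusted p = 4.91e-08, adjusted p = 0.19 with an estimated correlation). Of these, 3 rose adjusted over the list alone (0 to 5 without 1 array, 0 without NH3 array 1 or LPS array 4) and 0 over all genes, with Fdft1 at 0.22 (SE 0.06) and Insig1, which restrains sterol synthesis, at 0.40 (SE 0.13). Clock genes did not pass as a list (camera adjusted p = 0.0844). Adjusted over the list alone 2 rose and 3 fell (2 and 1 to 3 without 1 array), against 1 that fell over all genes: Npas2 at 0.35 (SE 0.09), Bmal1 at 0.32 (SE 0.10), Per1 at -0.29 (SE 0.11), Per3 at -0.20 (SE 0.07), and Per2.

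Choroid plexus and ependyma markers moved with ammonia too, with a median of 1.025 and all 13 positive (camera adjusted p = 1.9e-12, adjusted p = 0.19 with an estimated correlation). Of these, 11 rose adjusted over the list alone (0 to 13 without 1 array, 0 without any 1 of 14 arrays), against 0 over all genes. The list's mean was 1.07 ± 1.48 in NH3 (n = 5) and 0.20 ± 1.66 in NH3 + LPS (n = 4), against -0.35 ± 0.31 in PCA (n = 5). It was carried by 4 arrays: NH3 arrays 1, 2 and 5 and NH3 + LPS array 3. Ttr, the transthyretin gene and main choroid plexus transcript, was at 10.12 ± 3.02 in NH3 and 7.38 ± 1.86 in PCA (n = 5 each). Myelin genes had a median of 0.15, all 17 positive (camera adjusted p = 0.000901, adjusted p = 0.707 with an estimated correlation), and did not pass without NH3 + LPS array 3 (0.08, camera adjusted p = 0.0648). Microglial genes had a median of -0.176 with 17 of 18 negative (camera adjusted p = 3.99e-06, adjusted p = 0.461 with an estimated correlation), with C1qc at -0.40 (SE 0.14). Glucocorticoid response genes had a median of -0.10 (camera adjusted p = 0.00109, adjusted p = 0.19 with an estimated correlation), with 1 that fell adjusted over the list alone (1 to 3 without 1 array), the zinc finger gene Zbtb16, at -0.76 (SE 0.16). In all, 9 of 29 lists passed for this factor, and 1 did with an estimated correlation.

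**Figure D1:**
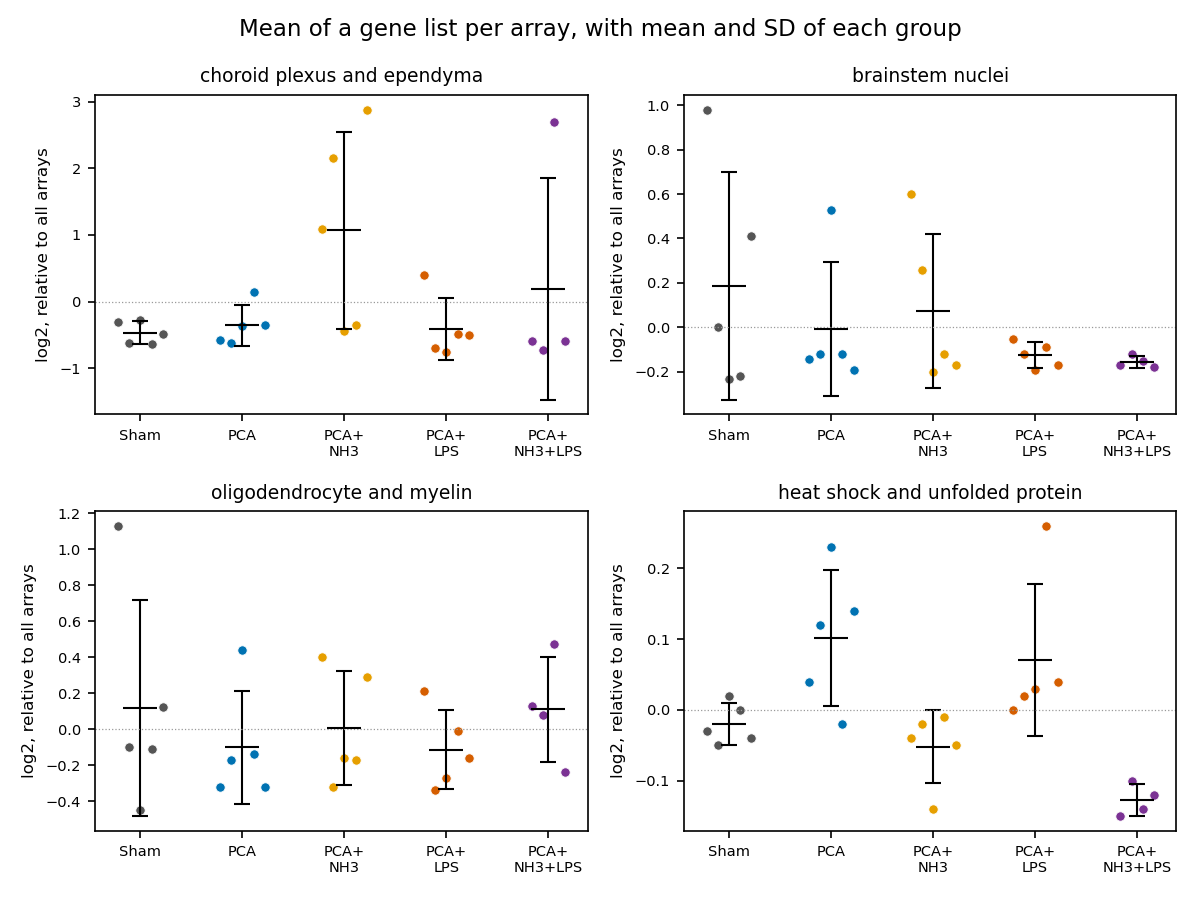
Mean of 4 gene lists in each array (log2, relative to the mean of all 24 arrays) by group, with points for arrays and bars for mean and SD. Choroid plexus markers were high in 3 NH3 arrays and 1 NH3 + LPS array. The heat shock list had a mean of -0.13 in NH3 + LPS against 0.10 in PCA, with NH3 at -0.05 and Sham at -0.02.

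NH3 against PCA asked what ammonia alone added to the shunt. No gene passed (0 with limma, 907 at an unadjusted p under 0.05). Dusp4 was closest at -0.96 (SE 0.16, limma adjusted p = 0.0578), with 5.64 ± 0.29 in NH3 and 6.60 ± 0.31 in PCA (n = 5 each), lower in 5 of 5 arrays than any PCA array. The others of smallest p were Pappa, a protease that releases insulin-like growth factor, at -1.24 (SE 0.26), Per2 at -0.82 (SE 0.19), Sipa1l2 at -0.70, the transcription factor Bach2 at -0.62, Creb5 at -0.42, Fgf16 at -0.42, Cmtm2a at 0.42, Cpped1 at 0.42 and Iqub at 0.38. Heat shock genes had a median of -0.14 (15 of 17 negative, camera adjusted p = 9.55e-06, adjusted p = 0.214 with an estimated correlation). Choroid plexus markers had one of 1.44 (13 of 13 positive, camera adjusted p = 2.54e-13, adjusted p = 0.319 with an estimated correlation). Of these, 8 rose adjusted over the list alone (0 to 12 without 1 array, 0 without any 1 of 16 arrays) and 0 over all genes. Cholesterol synthesis genes had a median of 0.18 (camera adjusted p = 8.68e-05, adjusted p = 0.63 with an estimated correlation), and interferon response genes one of 0.08 (camera adjusted p = 0.00146, adjusted p = 0.63 with an estimated correlation). The latter did not pass without NH3 array 1 (camera adjusted p = 0.14). Against Sham, 0 genes passed for NH3 with limma (1101 at an unadjusted p under 0.05, as many in 37 of 100 splits, the real one included). Choroid plexus markers were the 1 list that passed, with a median of 1.46 (camera adjusted p = 2.06e-13, adjusted p = 0.628 with an estimated correlation).

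The LPS factor asked what repeated LPS changed across both groups that received it, 9 arrays against 10. C3 rose by 1.75 on the log2 scale (SE 0.23, 3.36-fold, limma adjusted p = 0.00199), and all 9 LPS arrays lay above every one of the 10 others. Its level was 9.40 ± 0.41 in LPS (n = 5) and 9.18 ± 0.21 in NH3 + LPS (n = 4), against 7.68 ± 0.56 in PCA, 7.40 ± 0.75 in NH3 and 7.56 ± 0.62 in Sham (n = 5 each). Adgre1, the macrophage and microglia marker F4/80, rose by 0.78 (SE 0.13, limma adjusted p = 0.0238), above the mean of the others in 9 of 9 arrays. LOC299282, a gene known by a provisional symbol, rose by 0.33 (SE 0.06, limma adjusted p = 0.0496) at a low level of 3.66 ± 0.09 in LPS and 3.38 ± 0.11 in PCA (n = 5 each), with 9 of 9 arrays above every other. These 3 were chosen after their values were seen. C3 passed in all 24 fits that left out 1 array and in all 12 other alternatives, with an adjusted p from 3.07e-07 to 0.0155 over the latter, whereas Adgre1 passed in 13 and LOC299282 in 5 of the 24. The other table, among these 12, held the same values and could give no other result.

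In the antigen presentation list, 4 of the 6 genes of MHC class II, which presents antigen to T cells, rose for the LPS factor. Adjusted over the list alone these 4 of its 15 genes rose (4 without any 1 array), against 0 over all genes: Cd74, the class II invariant chain, at 1.04 (SE 0.24), RT1-Da at 0.83 (SE 0.19), RT1-Ba at 0.78 (SE 0.18) and RT1-Db1 at 0.33 (SE 0.09). The other 2 did not, RT1-DMa at -0.03 (SE 0.09) and RT1-DMb at 0.14 (SE 0.12), and were named after their values were seen. The list had a mean of 0.206 and a median of 0.028 (camera adjusted p = 0.00173, adjusted p = 0.535 with an estimated correlation). Cd74 was at 9.42 ± 0.63 in LPS (n = 5) and 9.82 ± 0.46 in NH3 + LPS (n = 4), against 8.74 ± 0.57 in PCA (n = 5). Complement genes had a median of 0.173 (9 of 10 positive, camera adjusted p = 5.81e-05, adjusted p = 0.535 with an estimated correlation), and C3 alone rose adjusted over that list (1 to 5 genes without 1 array). Microglial genes had a median of 0.094 (17 of 18 positive, camera adjusted p = 0.00516, adjusted p = 0.6 with an estimated correlation), with Itgam at 0.30 (SE 0.17). Choroid plexus markers were lower with a median of -0.435 (camera adjusted p = 0.00173, adjusted p = 0.6 with an estimated correlation), as were brainstem markers at -0.101 (camera adjusted p = 0.00619, adjusted p = 0.535 with an estimated correlation). The choroid plexus mean was -0.41 ± 0.47 in LPS and -0.35 ± 0.31 in PCA, against 1.07 ± 1.48 in NH3 (n = 5 each) and 0.20 ± 1.66 in NH3 + LPS (n = 4). That difference thus rested on the NH3 arrays, and without NH3 array 5 the median was -0.183. The microglial call ended without NH3 array 4, LPS array 1 or NH3 + LPS array 3 (camera adjusted p up to 0.0788), the choroid plexus call without NH3 array 5 or NH3 + LPS array 2 (up to 0.17), and the brainstem call without PCA array 3 or NH3 array 1 (up to 0.0825). In all, 12 of 29 lists passed for this factor, and 0 did with an estimated correlation.

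**Figure D2:**
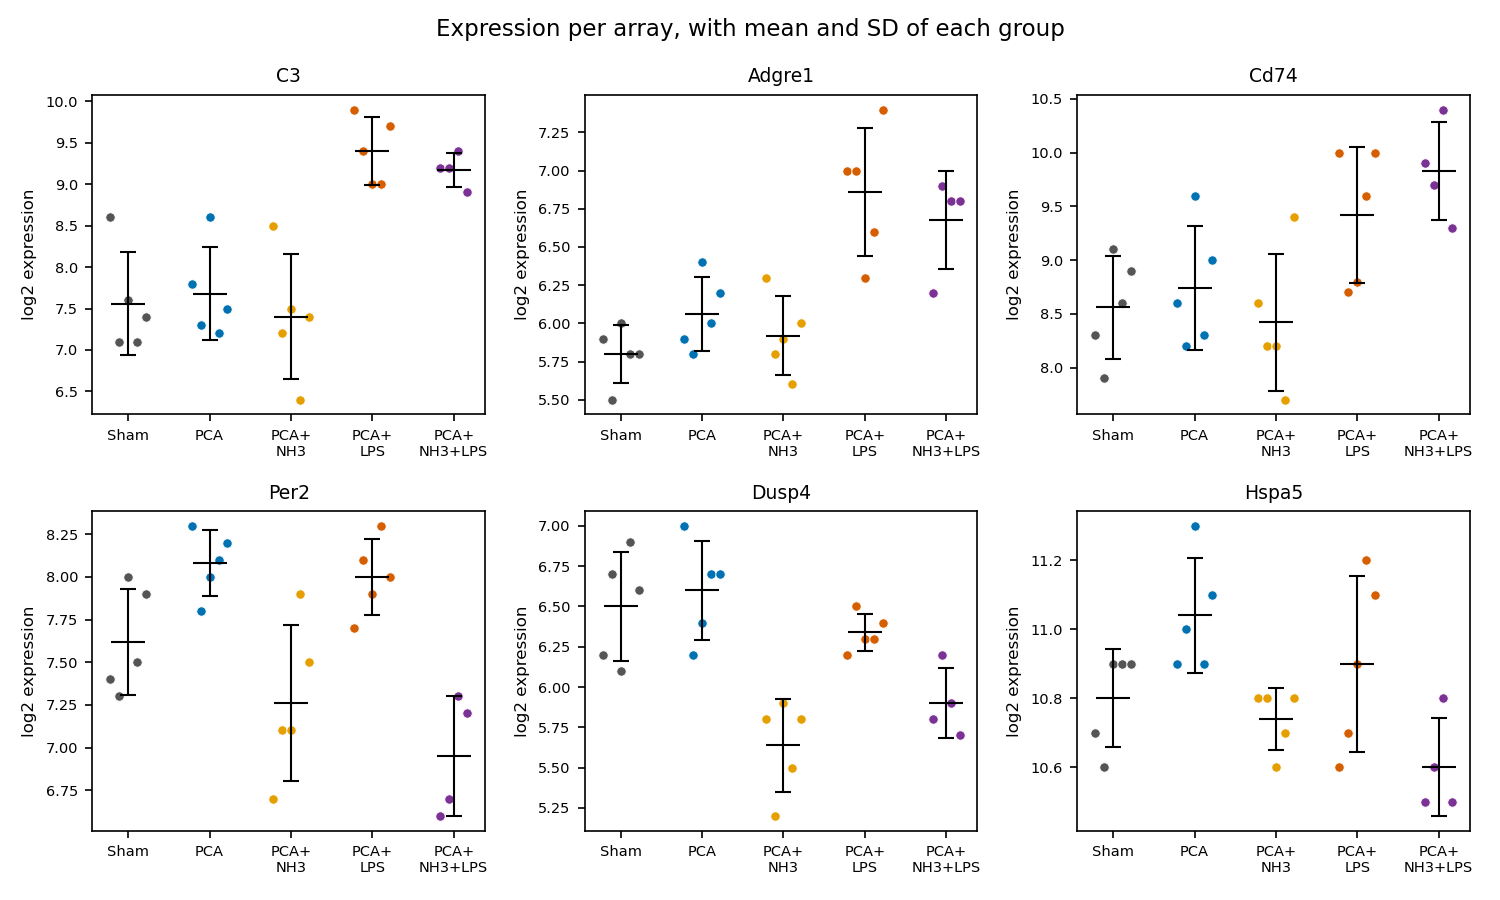
Expression of 6 genes in each array (log2) by group, with points for arrays and bars for mean and SD. C3 was 9.40 in LPS and 9.18 in NH3 + LPS against 7.68 in PCA, and Per2 was 7.26 in NH3 and 6.95 in NH3 + LPS against 8.08 in PCA.

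LPS against PCA asked what LPS alone added to the shunt. No gene passed (0 with limma, 728 at an unadjusted p under 0.05). C3 was at 1.72 (SE 0.32, limma adjusted p = 0.155), higher in 5 of 5 LPS arrays than any PCA array. Cxcl13, a chemokine that attracts B cells, was at 2.88 (SE 0.63, limma adjusted p = 0.454), with 7.86 ± 1.82 in LPS and 4.98 ± 0.40 in PCA (n = 5 each). The others of smallest p were Adgre1 at 0.80 (SE 0.17), the myeloid lectin gene Clec4a2 at 0.42, Cbr4 at 0.38, Bach2 at -0.68, Sipa1l2 at -0.68, Pde10a at -0.66, Ms4a2 at -0.34 and Tmprss2 at -0.30 (0.16 by its other, dimmer probe set). Complement genes, all 10 positive, had a median of 0.34 (camera adjusted p = 5.9e-08, adjusted p = 0.191 with an estimated correlation), with C1s at 0.52 (SE 0.20) and 1 that rose adjusted over the list alone (1 to 6 without 1 array), against 0 over all genes. Cytokine and NF-kB response genes had a median of 0.12 (19 of 25 positive, camera adjusted p = 0.00758, adjusted p = 0.579 with an estimated correlation), with Lcn2 at 1.02 (SE 0.50) and Il1b at 0.16 (SE 0.10). That list did not pass without LPS array 2 (camera adjusted p = 0.135). Blood cell genes had a median of 0.17 (9 of 12 positive, camera adjusted p = 0.0256, adjusted p = 0.579 with an estimated correlation), and did not pass without PCA array 5 or LPS array 2 or 5 (camera adjusted p up to 0.301). LPS arrays 2 and 5 had the highest means of the LPS group for blood cell genes (0.48 and 0.28), cytokine genes (0.42 and 0.31) and complement genes (0.61 and 0.65). In all, 9 of 29 lists passed, and 0 did with an estimated correlation.

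LPS against Sham, the shunt and LPS together, gave the most calls, 6 genes higher and 0 lower with limma (1359 at an unadjusted p under 0.05, as many in 25 of 100 splits, the real one included). Among them were C3 at 1.84 (SE 0.32, adjusted p = 0.03), Fmo2 at 1.40 (SE 0.25, adjusted p = 0.0339), and Pla1a at 1.2 (SE 0.20, adjusted p = 0.0198). The others were Adgre1 at 1.06 (SE 0.17, adjusted p = 0.0198), LOC100362769 at 0.96 (SE 0.14, adjusted p = 0.0119) and the carbonyl reductase gene Cbr4 at 0.48 (SE 0.09, adjusted p = 0.0339). For each, all 5 LPS arrays lay above all 5 Sham arrays, and all were chosen after their values were seen. Complement genes had a median of 0.59 (9 of 10 positive, camera adjusted p = 2.65e-09, adjusted p = 0.11 with an estimated correlation, fry adjusted p = 0.0315). Of these, 6 rose adjusted over the list alone (5 to 8 without 1 array), against 1 over all genes, with C1qa at 0.84 (SE 0.22) and C1qb at 0.68 (SE 0.16). Microglial genes had a median of 0.29 (17 of 18 positive, camera adjusted p = 3.39e-09, adjusted p = 0.285 with an estimated correlation). Of these, 7 rose adjusted over the list alone (4 to 10 without 1 array, 4 without Sham array 2), against 0 over all genes, with the leukocyte phosphatase gene Ptprc at 0.86 (SE 0.23) but at -0.04 (SE 0.09) by its other, dimmer probe set. Cytokine and NF-kB response genes had a median of 0.16 (camera adjusted p = 0.000158, adjusted p = 0.285 with an estimated correlation). Of these, 3 rose adjusted over the list alone (0 to 6 without 1 array, 0 without Sham array 2), against 0 over all genes: the iron-binding protein gene Lcn2 at 1.92 (SE 0.50), the monocyte chemokine gene Ccl2 at 1.74 (SE 0.52) and Casp1 at 0.38 (SE 0.12). Brainstem markers, all 14 negative, had a median of -0.27 (camera adjusted p = 0.00017, adjusted p = 0.285 with an estimated correlation), and myelin genes one of -0.24 (camera adjusted p = 0.00645, adjusted p = 0.702 with an estimated correlation). Both rested on Sham array 1, without which the medians were -0.08 (camera adjusted p = 0.0817) and -0.005 (camera adjusted p = 0.75), and the myelin call also ended without LPS array 2 (camera adjusted p = 0.0716). Blood cell genes had a median of 0.15 (10 of 12 positive, camera adjusted p = 0.0301, adjusted p = 0.431 with an estimated correlation), and did not pass without Sham array 2, 3 or 4 or LPS array 2 or 5 (camera adjusted p up to 0.257). With only the LPS and Sham arrays in the fit 0 genes passed, and 0 passed without LPS array 2 or without Sham array 4.

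NH3 + LPS against PCA asked what the combination added to the shunt. No gene passed (0 with limma, 755 at an unadjusted p under 0.05), and Per2 was closest at -1.13 (SE 0.20, limma adjusted p = 0.139), lower in 4 of 4 arrays than any PCA array. C3 was at 1.5 (SE 0.34), Dusp4 at -0.70 (SE 0.17), Sipa1l2 at -0.78, Gpr3, a receptor that raises cyclic AMP, at -0.52, Spred1, an inhibitor of MAP kinase signalling, at -0.44, the olfactory receptor gene Or52z1 at 0.51, Wsb1 at 0.47, Arsg at 0.45 and Iqub at 0.39. Per2, C3, Dusp4, Sipa1l2 and Iqub were also named in at least 1 other infusion contrast against PCA. These contrasts share the same PCA arrays, so the repeated differences are not separate evidence. Heat shock and unfolded protein genes fell as a group, with a median of -0.20 and 14 of 17 negative (camera adjusted p = 1.64e-11, adjusted p = 0.01 with an estimated correlation, fry adjusted p = 0.00541). Adjusted over the list alone 7 fell (3 to 10 without 1 array, 3 without PCA array 3, and 11 with cyclic loess), against 0 over all genes, with Hspb1 at -0.64 (SE 0.21), Sdf2l1 at -0.59 (SE 0.15), Hspa5 at -0.44 (SE 0.11) and Pdia4 at -0.30 (SE 0.08). Cholesterol synthesis genes had a median of 0.225 (14 of 15 positive, camera adjusted p = 1.98e-10, adjusted p = 0.114 with an estimated correlation). Of these, 3 rose adjusted over the list alone (0 to 5 without 1 array, 0 without PCA array 4 or NH3 + LPS array 1), against 0 over all genes, with Insig1 at 0.52 (SE 0.18) and Fdft1 at 0.34 (SE 0.09). Choroid plexus markers had a median of 0.61 and myelin genes one of 0.20 (camera adjusted p = 0.00641 and adjusted p = 0.83 with an estimated correlation for each). Without NH3 + LPS array 3 the choroid plexus median turned to -0.227 (camera adjusted p = 0.361) and the myelin median was 0.1 (camera adjusted p = 0.462). The myelin call also ended without PCA array 1 or 5.

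**Figure D3:**
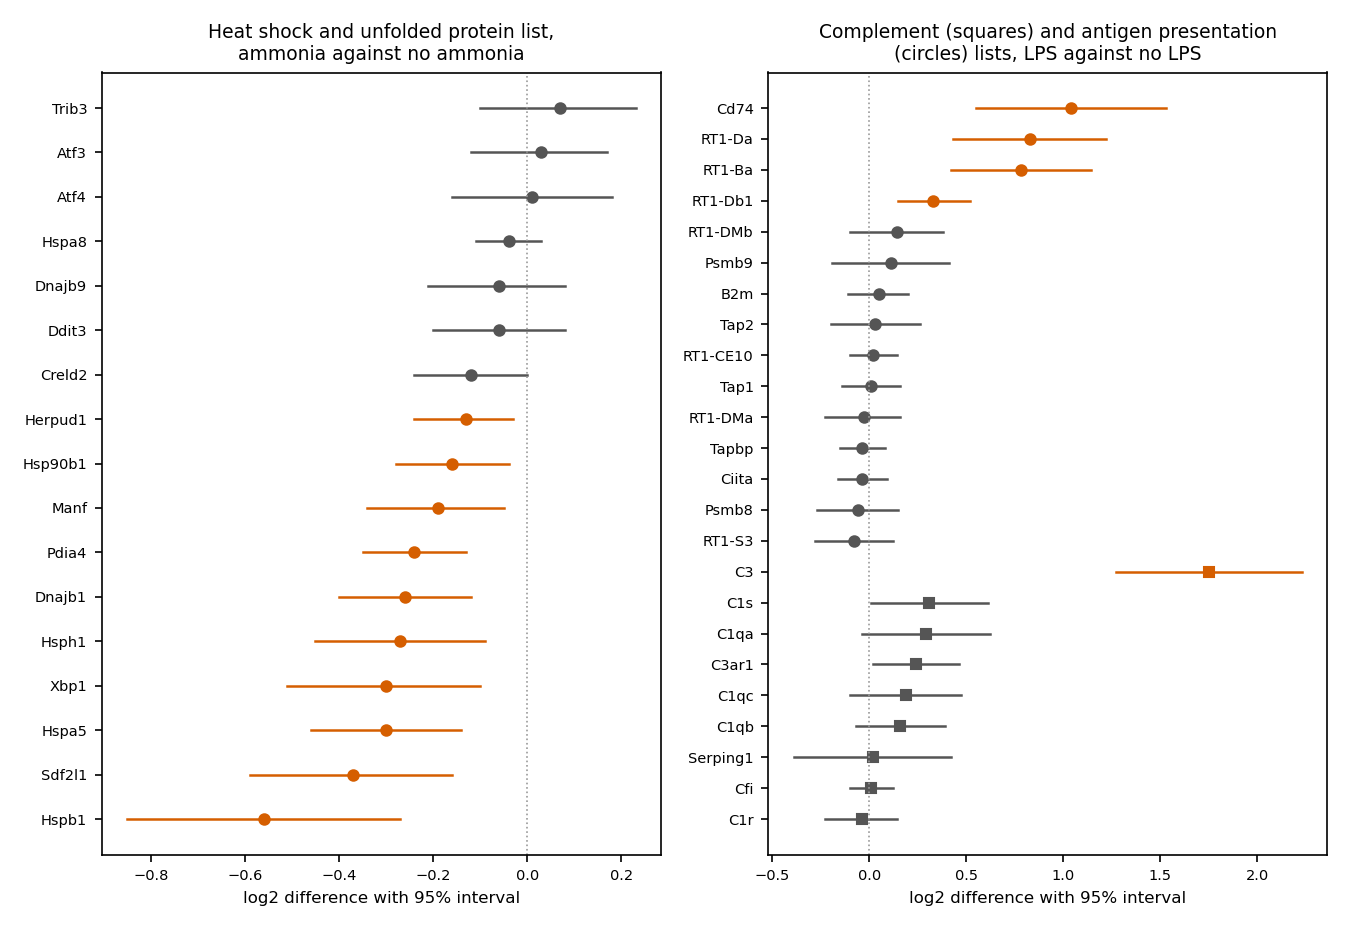
Differences (log2, horizontal axis) with 95% intervals for most members of 3 gene lists, 9 arrays against 10, with genes past 0.05 adjusted over their list alone in orange. In the heat shock list 10 genes lie below 0 in orange, and C3 at 1.75 and Cd74 at 1.04 lead their lists for LPS.

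NH3 + LPS against Sham set the full model against the surgical control. No gene passed (0 with limma, 729 at an unadjusted p under 0.05, smallest adjusted p 0.618). The genes of smallest p were C3 at 1.62 (SE 0.34), the class II gene RT1-Da at 1.18 (SE 0.28), Adgre1 at 0.88 (SE 0.18), the orphan nuclear receptor Nr4a3 at -1.50 (SE 0.38), Grpr at -0.70, Gpr3 at -0.58, the somatostatin receptor Sstr2 at -0.53, Galnt14 at -0.38, Tuba3b at -0.37 and Pde4d at -0.23. Immediate early genes had a median of -0.21 (12 of 15 negative, camera adjusted p = 1.5e-05, adjusted p = 0.402 with an estimated correlation). Of these, 4 fell adjusted over the list alone (0 to 6 without 1 array, 0 without NH3 + LPS array 1), against 0 over all genes, with Nr4a2 at -1.27 (SE 0.44), Fos at -1.17 (SE 0.40) and Nr4a1 at -1.10 (SE 0.39). Antigen presentation genes had a median of 0.07 (camera adjusted p = 0.0016, adjusted p = 0.402 with an estimated correlation). Of these, 3 rose adjusted over the list alone (1 to 4 without 1 array, 1 without NH3 + LPS array 3), against 0 over all genes, with Cd74 at 1.27 (SE 0.34) and RT1-Ba at 0.88 (SE 0.26). Clock genes had a median of -0.067 (camera adjusted p = 0.0462, adjusted p = 0.402 with an estimated correlation). Of these, 2 fell adjusted over the list alone (0 to 2 without 1 array, 0 without Sham array 3 or NH3 + LPS array 1 or 2), against 0 over all genes: Per2 at -0.67 (SE 0.20) and Per1 at -0.57 (SE 0.16). Brainstem markers had a median of -0.255 (camera adjusted p = 0.000503, adjusted p = 0.402 with an estimated correlation). Choroid plexus markers had one of 0.635 (camera adjusted p = 0.0016, adjusted p = 0.774 with an estimated correlation). Without Sham array 1 the brainstem median was -0.087 (camera adjusted p = 0.133), and without NH3 + LPS array 3 the choroid plexus median turned to -0.193 (camera adjusted p = 0.467). The antigen presentation call ended without Sham array 2 or NH3 + LPS array 3 (camera adjusted p up to 0.0786), and the clock call held in 14 of 24 fits that left out 1 array. In all, 10 of 29 lists passed, and 0 did with an estimated correlation.

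The interaction asked whether the combination differed from the sum of ammonia and LPS. No gene passed (0 with limma, 677 at an unadjusted p under 0.05, smallest adjusted p 0.997), and its median SE was 0.144. Immediate early genes had a median of -0.365 (11 of 15 negative, camera adjusted p = 0.000663, adjusted p = 0.573 with an estimated correlation), with Fos at -1.77 (SE 0.55), Nr4a1 at -1.46 (SE 0.54) and Dusp1 at -1.19 (SE 0.41). Complement genes had a median of -0.305 (9 of 10 negative, camera adjusted p = 0.0038, adjusted p = 0.573 with an estimated correlation), with C1qb at -0.48 (SE 0.23). Antioxidant genes of the Nrf2 pathway had a median of -0.14 (16 of 17 negative, camera adjusted p = 0.0065, adjusted p = 0.573 with an estimated correlation), with Hmox1 at -0.23 (SE 0.16), and did not pass without LPS array 1 (camera adjusted p = 0.0505). In all, 7 of 29 lists passed, all of them lower, and 0 did with an estimated correlation. The test for any difference among the 5 groups called 2 genes, C3 (limma adjusted p = 0.0181) and Adgre1 (limma adjusted p = 0.0422).

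Genes of prior interest in hepatic encephalopathy did not pass in any of the contrasts, and in all PCA groups against Sham or in the ammonia or LPS factor the difference changed sign or rounded to 0 in at least 1 alternative for Gfap, Aqp4, Slc1a2, Slc1a3, Calb1, Pcp2, Gabra6, Tspo, Aif1, Il1b, Tnf, Hmox1 and Ttr. For Aqp4, Hmox1 and Aif1 it did so only in the LPS factor, where they were at -0.06, -0.04 and 0.03. Over the alternatives Aqp4 stayed between -0.36 and -0.21 for all PCA groups against Sham and between 0.18 and 0.3 for ammonia. Gfap, the astrocyte filament gene, differed by 0.01 (SE 0.21) between all PCA groups and Sham, 0.17 (SE 0.19) for ammonia and -0.15 (SE 0.19) for LPS. Aqp4, the astrocyte water channel, was at -0.29 (SE 0.10), 0.24 (SE 0.09) and -0.06 (SE 0.09) in the same order. Lcn2 was at 1.05 (SE 0.40), -0.71 (SE 0.37) and 0.41 (SE 0.37), and kept its sign over the alternatives. The largest of these differences were in LPS against Sham, also not past the threshold. There Aqp4 was at -0.48 (SE 0.12), Hmox1 at 0.36 (SE 0.11) and Lcn2 at 1.92 (SE 0.50), with limma adjusted p = 0.319, 0.428 and 0.339. The glutamate transporter genes Slc1a2 and Slc1a3 were at -0.09 (SE 0.13) and 0.01 (SE 0.07) for all PCA groups against Sham. The inflammatory genes Il1b and Tnf were at 0.10 (SE 0.07) and 0.06 (SE 0.10) for LPS, and Aif1, a microglial marker, at 0.03 (SE 0.11). Tspo, a mitochondrial protein used to image glial activation, was at 0.13 (SE 0.14) for all PCA groups against Sham and -0.25 (SE 0.13) for ammonia, and the heme oxygenase gene Hmox1 at 0.21 (SE 0.09) and -0.21 (SE 0.08). The Purkinje cell genes Calb1 and Pcp2 were at 0.11 (SE 0.10) and 0.00 (SE 0.06) for all PCA groups against Sham, and the granule cell gene Gabra6 at 0.10 (SE 0.07). Genes of ammonia, glutamine and glutamate handling had a median of -0.056 for all PCA groups against Sham (camera adjusted p = 0.309) and 0 for ammonia (camera adjusted p = 0.95).

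Fold changes of contrasts sharing the PCA arrays were compared across 18161 genes, which are not independent replicates. NH3 and LPS against PCA correlated at 0.39, with 0.49 (0.18 to 0.83) in draws of unchanged groups that share the same arrays, and the covariance was 0.00651 against 0.00926. For NH3 and NH3 + LPS the correlation was 0.51 against 0.46 (0.11 to 0.75), with a covariance of 0.00836 against 0.00932, and for LPS and NH3 + LPS it was 0.41 against 0.45 (0.01 to 0.75), with 0.00602 against 0.00892. With separate PCA arrays for each contrast these correlations were -0.04, 0.04 and -0.07. PCA against Sham correlated at -0.34, -0.21 and -0.39 with NH3, LPS and NH3 + LPS against PCA, where unchanged groups gave -0.48 for each, with covariances of -0.00545, -0.00295 and -0.00554 against -0.009, -0.00903 and -0.00977. With separate PCA arrays these were 0.09, 0.21 and 0.09.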

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

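The test of how many ammonia arrays carried choroid plexus markers and the fits without 4 of them were chosen after the result was seen, as were the comparison of probe sets and that of class II with all microglial genes.

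Per2 and the heat shock genes were lower with ammonia than in the PCA and LPS groups. For the heat shock list, NH3 (-0.05 ± 0.05) lay near Sham (-0.02 ± 0.03), while PCA (0.10 ± 0.10) and LPS (0.07 ± 0.11) lay above it. Choroid plexus tissue as the cause of the Per2 difference was argued against, since without the 4 arrays with its markers the difference was -0.87 (SE 0.15, 95% interval -1.18 to -0.57) beside -0.93 (SE 0.14) with them. The call then ended with 4 arrays fewer and a larger SE (limma adjusted p = 0.169, with a range of 0.00374 to 0.169 over 12 alternatives other than single arrays). Lower body temperature may account for the pattern, because the cold-induced genes Cirbp at 0.29 (SE 0.10) and Rbm3 at 0.37 (SE 0.12) had a mean of 0.329 (95% interval 0.086 to 0.571), although neither passed over all genes (limma adjusted p = 0.753 and 0.654). Time of day at sampling cannot be told apart, as the largest difference among 6 other clock genes was 0.32 for Bmal1 (95% interval 0.12 to 0.52), with no sampling times in the labels, and an effect of ammonia itself stays open.

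Choroid plexus markers were high in 4 of the 9 ammonia arrays, with list means of 1.09, 2.16 and 2.88 in NH3 arrays 1, 2 and 5 and 2.69 in NH3 + LPS array 3. The other 5 lay within or below the range of the Sham and PCA arrays (-0.64 to 0.15), which is consistent with choroid plexus tissue left on at dissection. Chance placement of these arrays was not excluded, since an exact two-sided permutation test over 92378 splits of 9 ammonia arrays (0.68 ± 1.53) and 10 other PCA arrays (-0.38 ± 0.37) gave p = 0.0552. An effect of ammonia on the choroid plexus in some animals stays open and was not tested.

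C3 and 4 of 6 MHC class II genes were higher with LPS, the 4 adjusted over the antigen presentation list alone and 0 of the 6 over all genes, while RT1-DMa was at -0.03 (SE 0.09) and RT1-DMb at 0.14 (SE 0.12). More microglia with unchanged expression per cell were argued against as the whole cause. The 5 homeostatic microglial genes had a mean of 0.042 (95% interval -0.181 to 0.265), with an upper bound narrowly below 0.5 of the median of the 6 class II genes (0.556). The mean of the class II genes rose by 0.403 (95% interval 0.168 to 0.638) more than that of all 18 microglial genes. A flat mean would not show more microglia if each cell expressed less of these genes, and whole tissue cannot tell these apart. A smaller rise of microglia stays open too, as the 18 genes had a mean of 0.112 (95% interval -0.104 to 0.327, an upper bound not below that share) and a median of 0.094 (17 of 18 positive, camera adjusted p = 0.00516, adjusted p = 0.6 with an estimated correlation), and Adgre1 was at 0.78 (SE 0.13). Meninges or choroid plexus were argued against for C3, which was at 1.83 (95% interval 1.34 to 2.32, limma adjusted p = 0.00185) with the means of both lists as covariates beside 1.75 without, and had a limma adjusted p of 3.07e-07 to 0.0155 over 12 alternatives other than single arrays. Lymphocytes or neutrophils cannot be told apart from this pattern, as 8 of their genes had a mean of 0.09 (95% interval -0.049 to 0.229), too wide to decide, and the blood cell list, which adds red cell genes to them, had a median of 0.163 with LPS arrays 2 and 5 at 0.48 and 0.28. An immune response of resident cells to LPS may explain the pattern and stays a hypothesis.

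An array stood far from the others of its group in 40 of 450 sets of values (61 genes and 29 lists in 5 groups), where chance gives 1 in 20, or 22. The gap to the nearest array as a share of the group's range is given for each. A share of 1 means that all other arrays had the same value, which rounding to 0.1 favours.

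In Sham, array 1 stood apart for Gabra6 (1, at 11.8), Sertad4 (1, at 6.3), Fmo2 (0.75, at 6.1), Slc1a2 (0.727, at 11.5), Purkinje cell genes (0.844, at -0.50) and granule cell genes (0.798, at -0.55). Bach2 was highest in Sham array 2 (1, at 5.8), and Creb5 lowest in Sham array 5 (1, at 7.5). Clock genes were highest in Sham array 3 (0.806, at 0.21), and blood cell genes in Sham array 5 (0.762, at 0.05).

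In PCA, array 3 stood apart for brainstem markers (0.891, at 0.53), microglial genes (0.89, at 0.38), oligodendrocyte precursor genes (0.808, at 0.32), granule cell genes (0.776, at -0.26), myelin genes (0.76, at 0.44), pericyte genes (0.75, at 0.11) and Gabra6 (0.75, at 12). Creb5 was highest in PCA array 4 (0.8, at 8.3), and Lyn lowest in PCA array 2 (0.75, at 6.8).

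In NH3, Pde10a was lowest in array 3 (1, at 7.9), Sertad4 in array 2 (1, at 5.9) and Aif1 in array 4 (0.8, at 5.7), while Slc1a2 was highest in array 1 (0.8, at 11.1) and Wsb1 in array 2 (0.75, at 10). In LPS, array 1 was highest for Gfap (0.818, at 10.3), inhibitory interneuron genes (0.842, at 0.19) and choroid plexus markers (0.762, at 0.40). Heat shock genes were highest in LPS array 4 (0.86, at 0.26), and LPS array 3 was lowest for Pla1a (0.727, at 5.2) and glucocorticoid response genes (0.778, at -0.03).

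In NH3 + LPS, array 3 was highest for Ttr (0.97, at 12.5 with the next at 6.1), choroid plexus markers (0.957, at 2.69) and Wsb1 (1, at 10) and lowest for Desi2 (1, at 9.1) and Tuba3b (1, at 3.3). Array 1 was lowest for Adgre1 (0.857, at 6.2), Nr4a3 (0.909, at 5.1) and Grpr (1, at 3.2). Fxyd1 was lowest in array 2 (1, at 11.2), and Tg in array 4 (1, at 3.4).

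The interaction of ammonia and LPS passed for Bach2, at 0.85 (limma adjusted p = 0.00707 over the 61 named genes), and for Tmprss2, at 0.38 (limma adjusted p = 0.0303). Bach2 was at 6.2 ± 0.29 in PCA, 5.58 ± 0.19 in NH3, 5.52 ± 0.25 in LPS (n = 5 each) and 5.75 ± 0.17 in NH3 + LPS (n = 4). In Sham, array 2 was at 5.8 and the others at 5.7, so PCA without infusions was the group that stood apart. The PCA arrays enter the interaction and each infusion contrast against PCA, so these Bach2 differences are not separate evidence of an effect of ammonia or LPS. Tmprss2 was at 5.20 ± 0.07, 5.00 ± 0.10, 4.90 ± 0.12 and 5.08 ± 0.10. Both genes were named for small p-values in these same arrays, and neither passed over all genes, where the smallest limma adjusted p was 0.997. A dimmer probe set of Tmprss2 (mean 3.25 against 5.08) had an interaction of -0.10, the other direction.

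Among probe sets outside the gene test, 2 labelled with both Mt1a and LOC100362769 (10796411 and 10809392) were higher in LPS than in Sham by 1.48 and 1.52 (limma adjusted p = 0.00129 and 0.00117), and in all PCA groups than in Sham by 1.08 each (limma adjusted p = 0.00547). The first was at 8.36 ± 0.35 in Sham, 9.34 ± 0.35 in PCA, 9.32 ± 0.16 in NH3, 9.84 ± 0.44 in LPS (n = 5 each) and 9.25 ± 0.24 in NH3 + LPS (n = 4). A probe set with no symbol (10882905) was higher in LPS than in Sham by 0.46 (limma adjusted p = 0.0276), at a level of 3.40 ± 0.17 against 2.94 ± 0.05 (n = 5 each).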

How the results depend on the processing

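The myelin covariate, the fits without arrays with choroid plexus or brainstem markers and the added rounding noise were chosen after seeing the data, as were the permutations of sample numbers. C3 for the LPS factor passed in 24 of 24 fits without 1 array and in 12 of 12 other alternatives, and Per2 for the ammonia factor in 24 of 24 and 11 of 12. The 12 include the other table, which held the same values and could give no other result. The 24 include fits without a Sham array, which could not move the log2 difference of either factor. No gene past the threshold changed direction. Among genes of prior interest, differences changed sign or rounded to 0, for all PCA groups against Sham, in 12 alternatives for Gfap, 5 for Slc1a3, 4 each for Slc1a2 and Il1b, 2 each for Calb1 and Tnf and 1 each for Gabra6 and Tspo. They did so for the LPS factor in 4 for Aif1, 3 for Slc1a2, 2 each for Gfap, Aqp4, Hmox1 and Tspo and 1 for Tnf, and for the ammonia factor in 7 for Gabra6, 2 each for Il1b and Ttr and 1 each for Gfap and Slc1a2. Pcp2 rounded to 0 for all PCA groups against Sham with all arrays, and to a value other than 0 in 22 of 35 alternatives (range -0.03 to 0.04). The filter leaving out 25% of genes and camera with an intensity trend moved no count by over 1.5 times, and the other table, with the same values, could move none. Counts of genes moved by over 1.5 times as follows, and the cause was not tested, also where fewer arrays or genes entered. Trend and robust settings gave 1 for NH3 against PCA and 5 for any difference. Array weights gave 3, 2 and 4 for NH3, LPS and NH3 + LPS against PCA, 0 for all PCA groups against Sham and 7 for any difference. Without the dimmer 50% of genes there were 1 for the LPS factor, 4 for any difference and 48 gene lists. All probe sets gave 3 for all PCA groups against Sham, 1 for the ammonia factor and 4 for any difference. Cyclic loess gave 0 for all PCA groups against Sham, and adjusted over a list alone 11 heat shock genes for NH3 + LPS against PCA (7 before) and 1 cholesterol synthesis gene for PCA against Sham (2 before). The choroid plexus covariate gave 0 for that contrast, 1 for the ammonia factor and 6 for the LPS factor. The myelin covariate gave 1 for LPS against PCA, 1 for NH3 + LPS against Sham, 11 for LPS against Sham, 6 for the ammonia factor and 8 for any difference. Without the 4 choroid plexus arrays there were 3 for LPS against Sham, 0 for all PCA groups against Sham, 0 for the ammonia factor, 1 for the LPS factor and 1 for any difference. Without the 3 brainstem arrays there were 3, 2 and 1 for NH3, LPS and NH3 + LPS against PCA, 1 for NH3 + LPS against Sham and 0 for all PCA groups against Sham. Only the groups of a contrast gave 0 for LPS against Sham and 1 for the LPS factor. Rounding noise gave medians of 1 for NH3 against PCA and 0.5 for all PCA groups against Sham. Gene list calls over all contrasts numbered 82, against 2 with an estimated correlation and 3 with fry. With separate PCA arrays the correlations of fold changes were -0.04 (NH3 and LPS), 0.04 (NH3 and NH3 + LPS) and -0.07 (LPS and NH3 + LPS), and for PCA against Sham 0.09 (NH3), 0.21 (LPS) and 0.09 (NH3 + LPS), of which all but 0.04 changed sign.

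Arrays of different groups with the same sample number may share a source of variation, and 23 of their 46 pairs, not all, correlated above 0.1 (range -0.47 to 0.57). The mean correlation was 0.09 against -0.02 for different numbers (one-sided permutation p = 0.0106 over 10000 permutations). An array of the same number was the best correlated one for 12 of 24 arrays, where permuted numbers gave a mean of 4.83 (one-sided permutation p = 0.0045). The labels do not say what the numbers share. The sample number as a block gave 1 gene for LPS against PCA, 1 for the ammonia factor and 1 for any difference, and moved no other count by over 1.5 times. Equal counts hid other genes: with the block, 0 of 1 calls for all PCA groups against Sham was shared (LOC100362769 at 0.69, SE 0.11, limma adjusted p = 0.0546, beside 0.70, SE 0.11 and 0.0477, with a range of 0.00345 to 0.355 over all 35 alternatives), 3 of 6 for LPS against Sham, 1 of 3 for the ammonia factor and 2 of 3 for the LPS factor.

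Leaving out each array in turn gave 0 to 2 genes for NH3 against PCA (2 without PCA array 3, 1 without PCA 2 or Sham 1, 3 or 4), 0 to 2 for LPS against PCA (2 without PCA 3, 1 without LPS 5) and 0 to 1 for NH3 + LPS against PCA (1 without NH3 1 or 4). LPS against Sham ranged from 0 to 10 (0 without LPS 2 or Sham 4, 1 without LPS 1, 2 without LPS 4 or 5 or Sham 3, 10 without LPS 3). All PCA groups against Sham ranged from 0 to 1, with 1 kept only without PCA 1 or 4, NH3 5 or LPS 1, 3 or 5. The ammonia factor ranged from 1 to 4 (1 without PCA 1, 4 or 5, LPS 2 or 5, NH3 2 or NH3 + LPS 1, 3 or 4). The LPS factor ranged from 1 to 4 (1 without PCA 1, 2 or 4, LPS 1 or 2, NH3 2, 3 or 4 or NH3 + LPS 2 or 3). Any difference ranged from 0 to 4 (0 without NH3 2, LPS 1, 2 or 5 or NH3 + LPS 2 or 3, 1 without Sham 1, 2 or 4, PCA 1 or 5, NH3 3 or 5, LPS 4 or NH3 + LPS 4, and 4 without PCA 2, NH3 4 or LPS 3). Gene lists ranged from 66 to 97, and of the 82 calls 68 were kept without Sham 1, where 6 medians turned, and 65 without LPS 2, the fewest. The other contrasts had 0 in every such fit. The number of arrays and the rounding to 0.1 limit the precision.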

Other observations

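The tests of heat shock subsets and the fit without 4 arrays were chosen after the result was seen, and the splits of the samples were planned.

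Heat shock genes outside the endoplasmic reticulum and chaperones within it, some of them outside the heat shock list, were both lower with ammonia. Each of 13 heat shock genes outside it, including the mitochondrial Hspd1 and Hspe1, was negative in the ammonia factor (mean -0.173, 95% interval -0.25 to -0.097), and so was each of 13 chaperones of the endoplasmic reticulum (mean -0.182, 95% interval -0.255 to -0.108). For the LPS factor the first 13 genes had a mean of -0.015 (95% interval -0.091 to 0.061). The 13 chaperones of the endoplasmic reticulum were lower too, at -0.077 (95% interval -0.15 to -0.004, all 13 negative). The whole heat shock list had a median of -0.06 for the LPS factor (camera adjusted p = 0.0168, adjusted p = 0.535 with an estimated correlation). Without the 4 arrays with choroid plexus markers the heat shock list had a median of -0.177 in the ammonia factor (camera adjusted p = 0.0398 with an estimated correlation). A probe set labelled with the metallothionein gene Mt2A was at 11.34 ± 0.31 in Sham and 12.16 ± 0.68 in PCA (n = 5 each), and did not pass for all PCA groups against Sham (0.84, SE 0.19, limma adjusted p = 0.534).

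Further lists passed for the LPS factor with the preset correlation, and none of them with an estimated one. Cholesterol synthesis genes had a median of 0.073 (14 of 15 positive, camera adjusted p = 0.00173, adjusted p = 0.535 with an estimated correlation). Pericyte genes were at 0.093 (camera adjusted p = 0.00865, adjusted p = 0.535 with an estimated correlation). Cytokine and NF-kB response genes were at 0.07 (camera adjusted p = 0.043, adjusted p = 0.6 with an estimated correlation). Interferon response genes were lower, at -0.062 (16 of 21 negative, camera adjusted p = 0.0188, adjusted p = 0.6 with an estimated correlation). Blood cell genes were at 0.163 (9 of 12 positive, camera adjusted p = 0.0188, adjusted p = 0.535 with an estimated correlation), and did not pass without LPS array 2 or 5 or NH3 + LPS array 2 (camera adjusted p up to 0.178). Purkinje cell genes were at 0.082 (13 of 15 positive, camera adjusted p = 0.00353, adjusted p = 0.6 with an estimated correlation), and did not pass without PCA array 3 (camera adjusted p = 0.145). The pericyte call ended without NH3 + LPS array 2 or 3 (camera adjusted p up to 0.138) and the heat shock call without PCA array 3 or LPS array 2 (up to 0.096). In fits that left out 1 array the cytokine call held in 12 of 24 and the interferon call in 17 of 24.

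Other splits of the same arrays, 100 per contrast with the real one included, were counted for as many genes as the real split. Fewer than 5 splits, the limit set in advance, gave as many for the ammonia factor (1 of 100, real value 3, highest other 1) and the LPS factor (2, real value 3, highest other 14). The same held for LPS against Sham (2, real value 6, highest other 13) and all PCA groups against Sham (2, real value 1, highest other 303). Chance was not excluded by this, since the limit was not adjusted over the contrasts. The splits also took no account of sample numbers, although arrays of the same number resembled each other. These counts are those with all arrays. Without any 1 of 9 arrays the ammonia factor gave 1, as many as its highest other split, and without the 4 arrays with choroid plexus markers it gave 0. Without any 1 of 10 arrays the LPS factor gave 1. The other 2 counts rested on single arrays too: LPS against Sham gave 0 without LPS array 2 or Sham array 4, and all PCA groups against Sham gave 0 in 18 of the 24 fits that left out 1 array. The splits were not repeated in those fits, and at a count of 0 every split gives as many. The limit was not met for any difference (5, real value 2, highest other 67). In the contrasts with 0 genes all 100 splits gave as many, with the highest other at 2 for PCA against Sham, 0, 4 and 1 for NH3, LPS and NH3 + LPS against PCA, 45 for NH3 against Sham, 23 for NH3 + LPS against Sham and 1 for the interaction. Splits that called several times the real count point to a structure of the samples, and the first component of the arrays held 22.5% of the variance. That component was furthest from 0 in Sham array 1 (0.66), PCA array 3 (0.38) and NH3 array 1 (0.34), the 3 arrays with brainstem markers. Whether these arrays account for the splits was not tested.

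For the gene lists chance was not excluded in any contrast. As many lists came from 70 splits for PCA against Sham (real value 5, highest other 16), from 73, 12 and 72 for NH3, LPS and NH3 + LPS against PCA (real values 4, 9 and 4, highest other 17, 14 and 13), and from 97, 47 and 51 for NH3, LPS and NH3 + LPS against Sham (real values 1, 10 and 10, highest other 22, 21 and 20). They came from 17 for all PCA groups against Sham (real value 11, highest other 17), 24 for the ammonia factor (real value 9, highest other 18), 5 for the LPS factor (real value 12, highest other 16) and 34 for the interaction (real value 7, highest other 21). These counts are with the preset correlation, which takes genes of a list as nearly independent.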
